A study of Homo sapiens with 24 samples.

How the data were processed

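RNA was measured in 18 libraries in 6 groups of 3, namely naive, DMSO-activated and PF-9927-treated cells of the CD4+ and CD8+ lineages. Open chromatin was measured in 6 ATAC-seq libraries of CD3+ cells, 3 with DMSO and 3 with PF-9927. Groups, replicate numbers, times and the dose were taken from the labels. Per the labels' protocols, total RNA was made into libraries with standard Illumina methods, and strand use and the removal of ribosomal RNA are not given in the sources used here. Antisense and overlapping genes may therefore share reads.

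Gene expression was deposited as a table of TPM, made by the authors. Its values summed to 1000000 per library. The submitters' processing notes name hg19, STAR 2.5.2 and edgeR 3.16.5 for the RNA libraries, without saying which of them made the TPM. The header of the table, per the file headers, gives 87996134 to 112487082 reads per library and a read length of 101 bases. TPM keeps no read counts, so the authors' values were not tested with a count model. The table held 20776 genes, and 72 on chromosome Y or of the X-inactivation locus were left out, since the cells came from people. Of the 20704 kept, 95.7% of the gene identifiers were found in a table of gene names. No column of values per sample was left unmatched (0 columns).

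Splicing was deposited as 20 tables of the authors' comparisons, 5 event types for each of 4 comparisons on hg19. The caller's version is not given in the sources used here. Per the file headers, each cell of these tables lists read counts of the inclusion and the skipping form for 3 libraries, with the form lengths and inclusion levels from 0 to 1. The tables also hold the authors' p-value and FDR, which were used only where the authors' deposited table is named. The column that holds the DMSO libraries was settled from counts that were identical in both tables of a lineage (100% of shared events). The cells carry no replicate number. Events on chromosome Y or on unplaced sequences were left out, and gene symbols were assigned by overlap of coordinates.

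ATAC-seq was deposited as 1 peak list per library on hg38. Bowtie2 2.1.0 and MACS2 2.1.0 are named in the submitters' processing notes. Each row has a fold enrichment ratio, a −log10 p and a −log10 q, all of them values of the authors' peak caller, and the lowest −log10 p in the deposited lists was 2. These values were used only to rank or filter peaks within a list. Lines with the same start and end were merged into 1 peak. Read counts per region were not used here, and how reads were shifted for the transposase is not given in the sources used here.

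Genes with a mean of at least 1 TPM over the 18 libraries were tested (12622 genes). limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1), with a trend in the prior variance, over all 18 libraries in 1 fit of 6 groups. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. Fold changes on this scale understate those of weakly expressed genes. The difference of effects between lineages was a contrast of contrasts. The 27 gene lists with measured members were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. An erythroid marker list had 0 members above the filter. Counts of called list members are given over all genes, and for some lists also adjusted over the list alone. Other lists served as checks for B, monocyte, NK and plasmacytoid dendritic cells, for CD4 and CD8 lineage genes, for RNA quality (mitochondrial transcripts) and for library preparation (replication histones).

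Genes named in the text follow a rule fixed beforehand. Per comparison it takes the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap, with at least 5 TPM in the higher group and an official symbol. It adds up to 4 members of each list with the smallest adjusted p and a fixed set of genes that includes PRMT5, MDM4, IL2RG and IFNB1. Splicing events were named from the largest gains and losses with a mean of at least 50 reads, plus called events of the lists. A result for 1 gene is not reported here.

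Splicing events with at least 10 reads in each of 6 libraries were tested with limma on the logit of the inclusion level, after adding 0.5 to each count and dividing by the form length. An event was called at an adjusted p under 0.05 and a difference of at least 0.1. The median read number of the tested retained introns was 189 in CD4+ and 202 in CD8+ cells. Mean inclusion per library was compared by an exact permutation test of 3 against 3, two-sided, whose smallest p is 0.1. Peaks of the 6 ATAC-seq libraries were merged where they shared at least 1 base. Promoters were taken as 1 kb on each side of the start of a gene, from a RefSeq gene table on GRCh38 (the assembly of hg38), with the strand from the expression table. Peak numbers, summed length, median width and the Jaccard index of shared bases were compared by exact permutation tests. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 was used for these steps.

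The expression test was tested on simulated data with 200 changed genes for the CD4+ comparison of PF-9927 with DMSO. It recovered 1.5% of log2 changes of 0.5, 61% of changes of 1 and 92.5% of changes of 2. The splicing test recovered 0 of 200 simulated skipped exons changed by 0.4, and 7.9% when 3000 were changed. The test weighted by counting precision recovered 9% and 44.6%. The search for regions in 1 group recovered 200 of 200.

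The replicate numbers were checked by correlating deviations from the group means. Same-numbered DMSO and PF-9927 libraries had correlations of 0.58, 0.22 and 0.67 in CD4+ cells, 0.69, 0.60 and 0.22 in CD8+ cells, and 0.342, 0.281 and 0.203 for ATAC-seq. Naive and DMSO libraries of CD8+ cells had 0.23, 0.21 and 0.21. All of these exceed 0.1, so the numbers were taken to pair these samples, from the data and not from the labels. No libraries of a group held identical values, with correlations of 0.970 to 0.988 within groups.

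Alternatives tried for expression were another pseudocount (0.1 TPM), no filter on low values, quantile normalization, the replicate number as a block, a fit of only the groups compared, and leaving out each library. Those for splicing were other read minimums (20 reads, or a mean of 10), other differences (0.05 and 0.2), the authors' deposited FDR, and leaving out each library. Those for ATAC-seq were a −log10 q of at least 5, the same number of top peaks (118411) in each library, an overlap of 50% of the shorter peak, and leaving out each library. Chosen after seeing the data were the limits of 0.05 to 0.95 on mean inclusion, the weighting by counting precision, the fit of only the groups compared with the block, leaving out naive CD8+ libraries 1 and 3, and keeping for activation in CD4+ cells only the libraries of 1 shared number in the labels.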

Results

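RNA was sequenced from human CD4+ and CD8+ T cells that were isolated as naive cells from peripheral blood and then activated on plates coated with antibodies against CD3 and CD28 (the T cell receptor complex and its costimulatory receptor) in the presence of IL-2. For each lineage the files held naive cells, cells activated for 72 h with the solvent DMSO, and cells activated for 72 h with 300 nM of the compound PF-9927, with 3 libraries per group and 18 in all. The series title places the compound in a study of symmetric arginine dimethylation, mRNA splicing and the start of type I and type III interferon signalling. Splicing was tabulated from the same RNA libraries. Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts open DNA, in CD3+ T cells after 96 h with DMSO or PF-9927 (3 libraries each). The RNA libraries held 87996134 to 112487082 reads, of which 96.9% to 98.0% mapped. The labels do not say whether the replicates were separate donors or cultures. The p-values below therefore measure only the spread between these samples, which may be technical. For expression this spread is pooled over all 6 groups, the naive ones included. The mean log2 level of interferon-stimulated genes had an SD of 0.165 and 0.26 in naive CD4+ and CD8+ cells. It was 0.513 and 1.185 with DMSO and 0.686 and 0.674 with PF-9927, so p-values of these genes with PF-9927 may be too small. Expression levels are means ± SD in TPM (transcript abundance scaled to the library total, n = 3 libraries), log2 changes are on the log2(TPM + 1) scale ± SE, and adjusted p-values come from limma. Coordinates of genes and splicing events are on hg19.

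The first comparison asked which transcripts PF-9927 changed in activated CD4+ cells. Of 44 measured interferon-stimulated genes 12 fell and 0 rose with the compound (adjusted p = 1.3e-18 for the list by camera with its preset correlation, and adjusted p = 0.32 with an estimated correlation). IFIT1, an antiviral protein that binds foreign RNA (ENSG00000185745.8, chromosome 10, 91152303 to 91163745), was at 1.75 ± 0.94 TPM with PF-9927 and 41.7 ± 31.8 TPM with DMSO, a log2 change of −3.66 ± 0.90 (adjusted p = 0.031). IRF7, the transcription factor that amplifies interferon production (ENSG00000185507.15, chromosome 11, 612553 to 615999), went from 58.5 ± 28.3 to 10.6 ± 4.71 TPM (adjusted p = 0.0076). Of 22 measured target genes of p53, 12 rose and 0 fell (adjusted p = 2.5e-14, and 0.029 with an estimated correlation). PHLDA3, a p53-induced inhibitor of AKT (ENSG00000174307.5, chromosome 1, 201434620 to 201438365), went from 1.52 ± 0.769 to 18.1 ± 0.337 TPM, a log2 change of 2.96 ± 0.22 (adjusted p = 2.7e-06), and MDM2, the ubiquitin ligase of p53, went from 40.7 ± 2.26 to 134 ± 9.87 TPM (adjusted p = 8.5e-06).

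Adjusted over the list alone, 20 interferon-stimulated genes fell and 1 rose in CD4+ cells, with the replicate number as a block 22 fell, and the list's median log2 change was −1.22. Other members that fell were IFIT2 (−3.16), USP18 (−2.85), MX1 (−2.68) and ISG15 (−1.83). Of the p53 targets 15 rose and 1 fell adjusted over the list alone, with a median of 0.97. Those that rose over all genes tested included BAX, which promotes apoptosis (2.22), RRM2B, a ribonucleotide reductase subunit (1.35), and MDM2 (1.70). CDKN1A, the cell cycle inhibitor p21, had a change of 0.61 ± 0.33 that missed the threshold (adjusted p = 0.36, but 0.0407 in a fit of only the groups compared with the replicate block). Of 18 measured genes of the integrated stress and unfolded protein responses, 4 fell (6 adjusted over the list alone): CHAC1, a glutathione-degrading enzyme (−1.16), PCK2 (−1.11), SLC7A11, the cystine transporter (−1.07), and ATF4, the central transcription factor of the response (−0.42, a call lost without any 1 of the 6 libraries, adjusted p 0.0579 to 0.147). The list's median was −0.45 (adjusted p = 3.2e-08, and 0.025 with an estimated correlation, but 0.097 with an estimated correlation and the replicate number as a block).

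Of 18 measured cholesterol synthesis genes, 3 fell in CD4+ cells, among them DHCR7 (−0.88) and INSIG1, which restrains the pathway (−0.86). The count was also 3 adjusted over the list alone (median −0.36, adjusted p = 5.2e-07, and 0.025 with an estimated correlation). Of 28 measured splicing factors 5 rose (6 adjusted over the list alone), among them PRPF8, the central spliceosome protein (0.80 ± 0.09, adjusted p = 0.00015), and HNRNPH1 (0.82), with a list median of 0.28 (adjusted p = 0.0001, and 0.32 with an estimated correlation). PRMT5, the main enzyme of symmetric arginine dimethylation (chromosome 14, 23389720 to 23398794), was at 57.8 ± 19.4 TPM with PF-9927 and 50.1 ± 12.9 TPM with DMSO (log2 change 0.17 ± 0.29, adjusted p = 0.84). None of the 11 measured members of its complex and of the other arginine methyltransferases passed, nor did any of the 25 measured Sm and SMN proteins, which assemble the spliceosome's RNA particles. IL2RG, the shared receptor chain of IL-2, IL-7 and IL-15, fell from 632 ± 38.5 to 411 ± 15.3 TPM (adjusted p = 0.017), while JAK3, the kinase that binds it, rose by 0.88 (adjusted p = 0.0035). IL7R, the IL-7 receptor and a gene of naive cells, rose from 147 ± 42 to 412 ± 68.8 TPM (adjusted p = 0.0027), and LTA, the cytokine lymphotoxin alpha, fell from 440 ± 87.8 to 96.8 ± 30.3 TPM (adjusted p = 0.0024).

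The largest rises in CD4+ cells among genes outside these lists were those of EDA2R (3.18) and CMBL, a hydrolase (3.03 ± 0.19, from 1.48 ± 0.453 to 19.1 ± 2.15 TPM). They were followed by APOBEC3H, HDC, PRG4 and PDLIM1. The lists are not complete, so a gene outside them may still be a p53 target. In all, 374 genes rose and 166 fell among 12622 tested, and after quantile normalization 276 rose and 241 fell. The libraries of the groups did not overlap in 22.4% of the tested genes, where chance gives 10%. The count of 540 became 1012 with the replicate number as a block, but 10 rises and 0 falls in a fit of only the groups compared, in which PHLDA3, MDM2, CMBL, EDA2R and PDLIM1 passed among the genes named here. That fit with the replicate block as well, chosen after the data were seen, called 1087 genes. Without PF-9927 replicate 1 or 3 or DMSO replicate 1 or 2 the count of 540 became 278, 258, 304 and 259. Of 33 called genes named here, 16 kept the call without any 1 library. IFIT1 missed the threshold without any 1 of these 4 libraries (adjusted p up to 0.142) and ISG15 without any 1 of them or PF-9927 replicate 2 (up to 0.155), and MX1, IFIT2, USP18, CHAC1, SLC7A11, DHCR7, INSIG1, IL2RG, RRM2, CDC45, ID2, MDM4, APOBEC3H and PRG4 did so without at least 1 library (up to 0.161). The library labels carry a further number after the letter L, whose meaning is not given, and it differs between the CD4+ DMSO and PF-9927 groups, so that number and the compound cannot be told apart in this lineage.

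**Figure D1:**
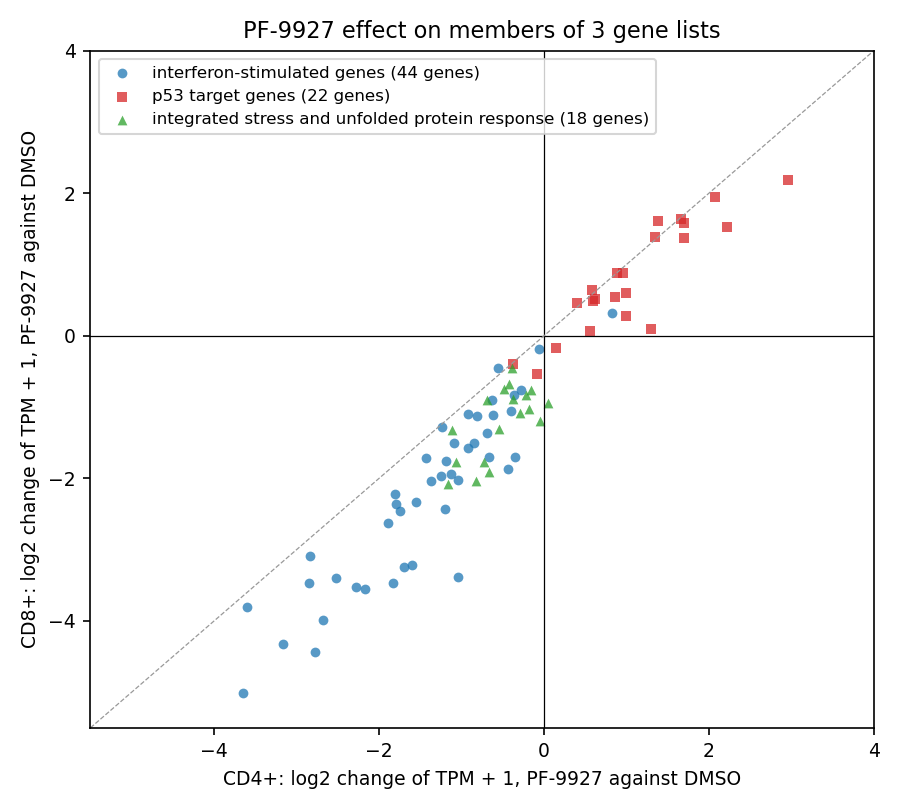
Log2 changes (TPM + 1) with PF-9927 against DMSO in CD4+ cells (horizontal axis) and CD8+ cells (vertical axis) for 44 interferon-stimulated genes (circles), 22 p53 targets (squares) and 18 stress response genes (triangles). Each point is one gene, and the dashed line marks equal changes. The medians were −1.22, 0.97 and −0.45 in CD4+ cells and −1.99, 0.62 and −1.05 in CD8+ cells.

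The same comparison in CD8+ cells, whose DMSO and PF-9927 libraries share this number, gave 25 falls and 0 rises among 44 interferon-stimulated genes (adjusted p = 2.3e-21, and 0.26 with an estimated correlation). IFIT1 was at 2.77 ± 2.88 TPM with PF-9927 and 187 ± 210 TPM with DMSO (−5.01 ± 0.90, adjusted p = 0.0035), IRF7 at 7.11 ± 3.74 and 151 ± 74.1 TPM (adjusted p = 6e-05), and ISG15 at 70.0 ± 26.3 and 930 ± 612 TPM (adjusted p = 0.00061). Adjusted over the list alone 37 fell, and with the replicate block 38, with a median of −1.99. Genes of the stress responses fell in 14 of 18 cases (17 adjusted over the list alone), with a median of −1.05 (adjusted p = 1.5e-15, and 0.0026 with an estimated correlation). Among them, CHAC1 changed by −2.08, ATF3 went from 59.3 ± 11.9 to 13.8 ± 3.63 TPM, and TRIB3 from 102 ± 16 to 29.3 ± 5.89 TPM, both targets of ATF4. Of 22 p53 targets 10 rose (12 rose and 2 fell adjusted over the list alone), with a median of 0.62 (adjusted p = 3.6e-09, 0.18 with an estimated correlation, and 0.043 with an estimated correlation and the block).

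CMBL (3.79) and the p53-induced oxidoreductase gene TP53I3 (3.37 ± 0.17, from 3.40 ± 0.484 to 44.4 ± 5.08 TPM, adjusted p = 2.2e-08) had the largest rises in CD8+ cells, followed by SULF2, PDLIM1 and EDA2R. Of 20 measured nucleic acid sensing genes 8 fell (11 adjusted over the list alone), with a list median of −0.73 (adjusted p = 1.4e-06 by camera, and 0.25 with an estimated correlation). Among them were DHX58, an RNA sensor of the RIG-I family (−2.05), and TRIM25, which activates RIG-I (−1.36). Whether their fall was a cause or a result of lower interferon signalling was not tested. Of 10 measured interferons, receptors and factors of their signalling, 4 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 0.031, and 0.20 with an estimated correlation). IFNB1, the gene of interferon beta, went from 8.03 ± 7.35 to 0.636 ± 0.745 TPM (adjusted p = 0.018), STAT2 changed by −1.42 and IRF9 by −0.94, and the receptor gene IFNAR2 rose by 0.72. In CD4+ cells none of these 10 and 1 of the 20 sensing genes passed (adjusted p = 0.089 and 0.00014 for the lists, the latter 0.32 with an estimated correlation), and IFNB1 was at 0.134 ± 0.232 TPM with PF-9927 and 2.29 ± 1.47 TPM with DMSO (adjusted p = 0.14). IFNL1, a type III interferon, lay below the expression filter, at 0.528 ± 0.561 TPM with PF-9927 and 3.05 ± 2.99 TPM with DMSO in CD8+ cells.

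Activation markers fell in 5 of 24 cases in CD8+ cells (adjusted p = 0.0011, and 0.25 with an estimated correlation), among them LAG3, an inhibitory receptor, from 202 ± 11.4 to 43.1 ± 21.5 TPM, SLC3A2, the shared chain of amino acid transporters (−1.39), PDCD1 (−1.31) and MYC (−1.12). Of 17 glycolysis genes 4 fell, such as PFKL (−0.92) and ALDOA (−0.74) (adjusted p = 2.2e-05, and 0.25 with an estimated correlation). Of 16 genes of the gamma chain cytokine pathway 3 fell (adjusted p = 0.033, and 0.37 with an estimated correlation), namely IL2RG (−0.55 ± 0.14), IL15RA (−1.49) and PIM1 (−0.81). Of 28 splicing factors 3 rose (7 adjusted over the list alone, adjusted p = 0.00031, and 0.32 with an estimated correlation), with PRPF8 at 0.72 and HNRNPH1 at 0.83. None of 18 cholesterol synthesis genes passed (median −0.03, adjusted p = 0.59), although INSIG1 did with the replicate block (−0.66, adjusted p = 0.0237). LTA (−2.35) and TNF (−1.29) fell and TNFSF11, the ligand RANKL, rose (1.59) among 21 cytokines. PRMT5 was at 56.6 ± 15.6 TPM with PF-9927 and 52.5 ± 12.8 TPM with DMSO (adjusted p = 0.88). Of the markers of other cells, CD68, a macrophage protein, fell (−2.02), and the CD4 transcript was at 3.28 ± 3.22 TPM with PF-9927 and 15.2 ± 10.8 TPM with DMSO (adjusted p = 0.017). None of 13 mitochondrial transcripts passed, but their median was 0.24 (adjusted p = 0.031, and 0.30 with an estimated correlation).

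In all, 469 genes rose and 636 fell with PF-9927 in CD8+ cells, but 576 rose and 548 fell after quantile normalization, and 26.4% of the tested genes had libraries that did not overlap (10% by chance). The count of 1105 became 1900 with the replicate block, but 84 rises and 78 falls in a fit of only the groups compared. That fit with the replicate block as well, chosen after the data were seen, called 1597 genes. Without PF-9927 replicate 2 or 3 or DMSO replicate 3 the count of 1105 became 594, 446 and 402. Of 47 called genes named here 25 kept the call without any 1 library. TNF, KLRD1, FOXP3 and CDC45 missed the threshold without any 1 of 5 of the 6 libraries (adjusted p up to 0.205), IFNB1 without PF-9927 replicate 3 or DMSO replicate 2 or 3 (up to 0.0825), and TNFSF11, CD68, the CD4 transcript, IL2RG, IL15RA, PIM1, MYC, PDCD1, ALDOA, PFKL, IFNAR2, STAT2, IL7R, TOB1, CD3G, PRF1 and RRM2 without at least 1 library (up to 0.126).

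**Figure D2:**
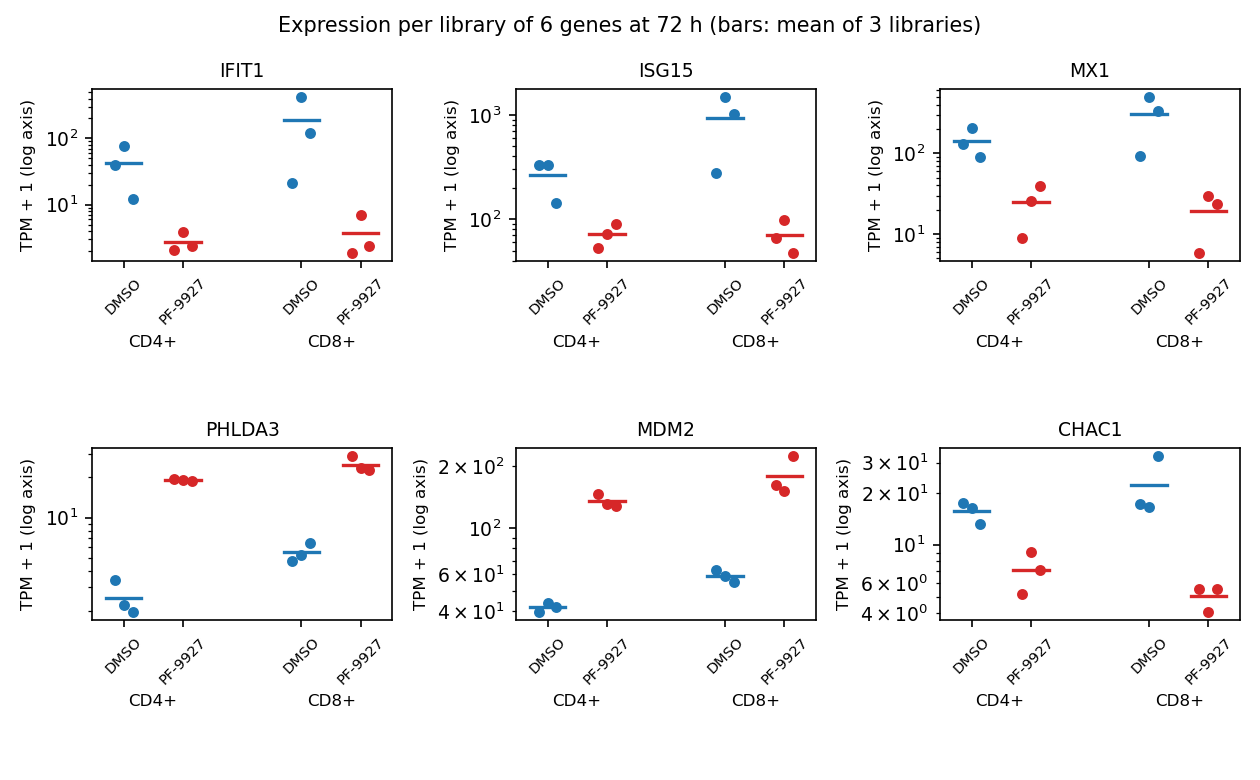
TPM + 1 per library (log axis) of 3 interferon-stimulated genes (IFIT1, ISG15, MX1), 2 p53 targets (PHLDA3, MDM2) and 1 stress response gene (CHAC1) at 72 h. Points are libraries and bars the mean of 3 libraries. In each panel and lineage the 3 PF-9927 libraries lie apart from the 3 DMSO libraries.

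The remaining lists held few or no calls with PF-9927. In CD4+ cells these were 24 activation markers (0 called, adjusted p = 0.013, and 0.32 with an estimated correlation), 17 glycolysis genes (0 called, adjusted p = 3.3e-05, and 0.29 with an estimated correlation) and 22 DNA repair genes (0 called, adjusted p = 0.014, and 0.41 with an estimated correlation). Of 23 replication genes 2 fell, RRM2 (−1.64) and CDC45 (−0.65) (adjusted p = 0.0015, and 0.32 with an estimated correlation). In CD8+ cells 2 replication genes fell, 1 DNA repair gene rose and 2 fell, and 1 Sm or SMN gene rose and 1 fell. Mitotic genes gave 0 calls of 24 in CD4+ cells and 1 rise in CD8+ cells, with MKI67, the proliferation marker, at −0.19 ± 0.31 in CD4+ and CD8+ cells alike. Of 21 genes of naive or quiescent cells 2 rose in each lineage, IL7R in both, SATB1 in CD4+ and TOB1 in CD8+ cells. The 17 helper lineage regulators gave 1 rise in CD4+ cells, ID2, and 1 fall in CD8+ cells, FOXP3. Of 14 cytotoxic genes none passed in CD4+ cells, and KLRD1 rose and PRF1 fell in CD8+ cells. Of 20 nuclear genes of oxidative phosphorylation 1 rose in each lineage. None of the B cell (3 measured), NK cell (2), plasmacytoid dendritic cell (2) and replication histone (6) genes passed in either lineage. Of 7 monocyte markers none passed in CD4+ cells, of 9 lineage markers none did in CD4+ cells, and CD3G rose in CD8+ cells. No mitochondrial transcript passed in CD4+ cells. With the replicate block, lists without a call gained some: in CD4+ cells 1 Sm or SMN gene and 1 DNA repair gene rose, and 2 DNA repair genes and 1 glycolysis gene fell, and in CD8+ cells 1 NK cell, 1 mitochondrial and 1 histone gene rose. In a fit of only the groups compared with the block, chosen after the data were seen, ALDOA (−0.46), CD3G (0.52), the CD4 transcript (−0.56), FOXP3 (−0.86), KLRD1 (0.83) and TNF (−1.03) passed in CD4+ cells (adjusted p 0.0276 to 0.0471).

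Whether the effect of PF-9927 differed between the lineages was tested directly. Across genes, which are not independent replicates, the log2 changes in CD4+ and CD8+ cells had a Pearson correlation of 0.61 and a Spearman correlation of 0.70. Of the genes that rose, 216 did so in both lineages, where independent lists would share 13.9, and of those that fell 138 did so in both, against 8.4. Deviations of same-numbered CD4+ and CD8+ libraries correlated at a mean of 0.295, against −0.144 for unequal numbers, so the lineages may not be unrelated samples. The test of the difference itself called 0 genes by limma (397 at an unadjusted p under 0.05). Of the lists, the stress response genes had a more negative change in CD8+ cells (median difference −0.73, adjusted p = 1.8e-10, and 0.012 with an estimated correlation, but 0.069 with the block as well). Cholesterol synthesis genes had a less negative change in CD8+ cells (median difference 0.34, adjusted p = 3.7e-08, and 0.012 with an estimated correlation, but 0.054 with the block as well). For interferon-stimulated genes the median difference was −0.67 (adjusted p = 3.7e-05, and 0.60 with an estimated correlation).

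Activation itself, the comparison of DMSO-treated with naive cells, called 7555 of 12622 tested genes in CD4+ and 8103 in CD8+ cells. GZMB, a protease of cytotoxic granules, was at 2.07 ± 1.93 TPM in naive and 2556 ± 1650 TPM in activated CD4+ cells (9.60 ± 0.76, adjusted p = 4.3e-08), and KLF2, a transcription factor of quiescent T cells, went from 613 ± 51.4 to 7.31 ± 5.95 TPM (adjusted p = 4e-06). In CD8+ cells GZMB rose by 10.35 and IL2RA, the high-affinity IL-2 receptor chain, went from 4.58 ± 3.47 to 856 ± 90.5 TPM. Every measured replication gene (23 of 23), mitotic gene (24 of 24) and glycolysis gene (17 of 17) rose in both lineages, with medians of 4.31, 6.15 and 3.22 in CD4+ and 4.50, 5.68 and 3.28 in CD8+ cells. The estimated correlation gave these lists an adjusted p of 0.022, 0.032 and 0.032 in CD4+ cells and 0.045, 0.049 and 0.049 in CD8+ cells, and with the block as well 0.079, 0.079 and 0.089 in CD8+ cells. Cholesterol synthesis (16 of 18) and DNA repair genes (20 of 22) rose in both lineages, with medians of 2.12 and 3.07 in CD4+ and 1.89 and 3.05 in CD8+ cells (adjusted p = 0.022, 0.029, 0.045 and 0.045 with an estimated correlation, and 0.079 and 0.12 with the block as well in CD8+ cells).

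Of 44 interferon-stimulated genes 25 rose with activation in CD4+ cells (median 1.61, adjusted p = 0.0027, and 0.70 with an estimated correlation) and 36 in CD8+ cells (median 2.19, adjusted p = 9.5e-05, and 0.56 with an estimated correlation). ISG15 was at 65.3 ± 4.45 TPM in naive CD4+ cells, and IFIT1 at 6.74 ± 4.4 TPM in naive CD4+ and 2.62 ± 2.14 TPM in naive CD8+ cells. Stress response genes rose in 14 and 16 of 18 cases (medians 2.30 and 2.92, adjusted p = 0.051 and 0.045 with an estimated correlation, and 0.11 with the block as well in CD8+ cells), with ATF3 at 3.95 and 5.48. PRMT5 rose from 20.2 ± 4.69 to 50.1 ± 12.9 TPM in CD4+ cells (adjusted p = 0.0015) and from 14.2 ± 2.3 to 52.5 ± 12.8 TPM in CD8+ cells (adjusted p = 6.3e-05). Of its 11-member list 6 rose and 2 fell in CD4+ cells, and 7 rose and 2 fell in CD8+ cells. Sm and SMN genes rose in 21 and 22 of 25 cases (adjusted p = 0.22 and 0.27 with an estimated correlation), whereas of 28 splicing factors 6 rose and 10 fell in each lineage. Genes of naive and quiescent cells fell in 15 of 21 cases in each lineage (adjusted p = 0.052 and 0.051 with an estimated correlation). MDM4, a p53 inhibitor, went from 62.3 ± 5.97 to 16.5 ± 0.998 TPM in CD4+ cells.

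The other lists, given as rises and falls in CD4+ and then in CD8+ cells, were activation markers (18 and 2, then 21 and 1 of 24, adjusted p = 0.051 and 0.049 with an estimated correlation), cytokines (15 and 0, then 13 and 0 of 21), oxidative phosphorylation (16 and 1 in each, of 20), p53 targets (9 and 5, then 15 and 1 of 22), nucleic acid sensing (11 and 3, then 12 and 5 of 20), interferons and receptors (4 and 2, then 6 and 1 of 10), and cytotoxic genes (6 and 2 in each, of 14). Helper regulators gave 5 and 4, then 6 and 2 of 17, gamma chain genes 8 and 4, then 10 and 2 of 16, and lineage markers 2 and 4, then 3 and 3 of 9. Replication histones gave 0 and 0, then 3 and 0 of 6, B cell markers 0 and 1, then 1 and 2 of 3, NK cell markers 0 and 1 in each, of 2, and plasmacytoid dendritic cell markers 0 and 0, then 0 and 2 of 2. Of 7 monocyte markers 1 rose in CD4+ cells, and 1 rose and 5 fell in CD8+ cells (median −4.69). Of 13 mitochondrial transcripts 1 rose and 4 fell in CD4+ cells and 8 fell in CD8+ cells (median −0.55, adjusted p = 0.002, and 0.11 with an estimated correlation, but 0.70 after quantile normalization).

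In all, 3833 genes rose and 3722 fell with activation in CD4+ cells, and 4920 rose and 3183 fell in CD8+ cells, with libraries that did not overlap for 65.0% and 68.3% of the tested genes (10% by chance). Quantile normalization moved the median change of all genes from 0.00 to −0.12 in CD4+ and from 0.18 to −0.11 in CD8+ cells, and the split became 3409 rises and 4331 falls in CD4+ and 3706 rises and 4420 falls in CD8+ cells. In the naive CD8+ libraries mitochondrial transcripts took 32.9 ± 2.24% of the TPM, against 22.8 ± 0.789% in the activated DMSO libraries. The largest falls in CD8+ cells were those of neutrophil granule genes such as LTF, CAMP and DEFA3, a defensin with near-identical copies that the counting may not separate. Naive CD8+ library 2 held LTF at 10.6 and CAMP at 10.9 TPM, against at most 0.3 and 0.2 TPM in the 15 libraries of the other groups. LTF was far higher, at 400.3 and 745.1 TPM, in naive CD8+ libraries 1 and 3. Without those libraries, a choice made after the data were seen, 3655 genes rose and 2354 fell. The number after the letter L differs between the naive and DMSO libraries of CD8+ cells and cannot be told apart from activation there, whereas within the number that 2 naive and 2 DMSO libraries of CD4+ cells share, 6217 genes were called, 6098 of them among the 7555.

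The difference in activation between the lineages gave 19 genes, 15 with a higher and 4 with a lower change in CD8+ cells. CTSW, a protease of cytotoxic cells (difference 1.93, adjusted p = 0.015), and XCL1, a chemokine of CD8+ cells (4.39, adjusted p = 0.036), were on the higher side, and IL21, a cytokine of helper T cells (−5.74, adjusted p = 0.036), on the lower. These genes were chosen after their values were seen. Naive CD8+ libraries 1 and 3, which hold neutrophil granule transcripts, enter this difference. So does the number after the letter L, which differs between naive and DMSO libraries of CD8+ cells. Leaving out 1 library gave between 2 genes (without naive CD8+ replicate 3) and 260 (without naive CD8+ replicate 2). The replicate block gave 114 genes, quantile normalization 5, and a fit of only the groups compared 5. Across genes, the activation changes of the lineages had a Pearson correlation of 0.91, with 3629 shared rises (1494 for independent lists) and 2857 shared falls (939).

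Whether PF-9927 moved the activation genes back towards naive levels was asked with the activation calls of the other lineage, which share no library with the PF-9927 comparison. In CD4+ cells the 4920 genes that rose with activation had a median PF-9927 change of −0.04 (interquartile range −0.24 to 0.14) and the 3183 that fell one of 0.20, against 0.06 for all genes. In CD8+ cells the medians were −0.10 for 3833 rising genes and 0.09 for 3722 falling genes, against 0.00 for all genes. PF-9927 raised 58 and lowered 118 of the rising genes in CD4+ cells, and 77 and 323 in CD8+ cells. It raised 206 and lowered 10 of the falling genes in CD4+ cells, and 264 and 99 in CD8+ cells. Within a lineage the comparisons share DMSO libraries. The covariance of their changes was −0.188 in CD4+ and −0.249 in CD8+ cells, where 100 simulations of unchanged groups against the same controls gave −0.0644 and −0.0639, differences of −0.123 and −0.185. The correlations, −0.319 and −0.338, were closer to 0 than the simulated −0.501 and −0.497. The simulated groups hold no activation change, whereas activation called 7555 genes in CD4+ and 8103 in CD8+ cells. Observed and simulated correlations therefore cannot be set against each other. The median PF-9927 change of genes that rose with activation in the same lineage was −0.048 in CD4+ and −0.116 in CD8+ cells. The simulated medians were −0.123 and −0.099. For falling genes the medians were 0.183 and 0.138, and the simulated ones 0.127 and 0.142. As the simulated groups hold no activation change, no conclusion is drawn from these medians either.

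Splicing was compared for skipped exons, retained introns, alternative 5′ and 3′ splice sites and mutually exclusive exons. Retained introns had higher inclusion with PF-9927 in both lineages. The mean inclusion level over 2360 retained introns in CD4+ cells was 0.589 ± 0.0019 with DMSO and 0.618 ± 0.0049 with PF-9927, a difference of 0.0292. Over 2570 introns in CD8+ cells it was 0.608 ± 0.0076 and 0.641 ± 0.0027, a difference of 0.0331. In each lineage all 3 PF-9927 libraries lay above all 3 DMSO libraries (two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). Inclusion was higher in 66.9% of the introns in CD4+ and 70.0% in CD8+ cells. Skipped exons had a mean inclusion that was lower by 0.0084 in CD4+ and lower by 0.0064 in CD8+ cells (exact p = 0.1 for each). Mean inclusion of retained introns was higher in naive than in DMSO-activated cells. Activation changed it by −0.0249 in CD4+ and −0.0374 in CD8+ cells (exact p = 0.1 for each). Naive libraries also had more bases covered, at 6.002 ± 0.868% against 4.941 ± 0.721% with DMSO in CD4+ cells. In CD8+ cells it was 6.477 ± 1.09% against 5.257 ± 0.413%, and whether this goes with the retention was not tested.

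**Figure D3:**
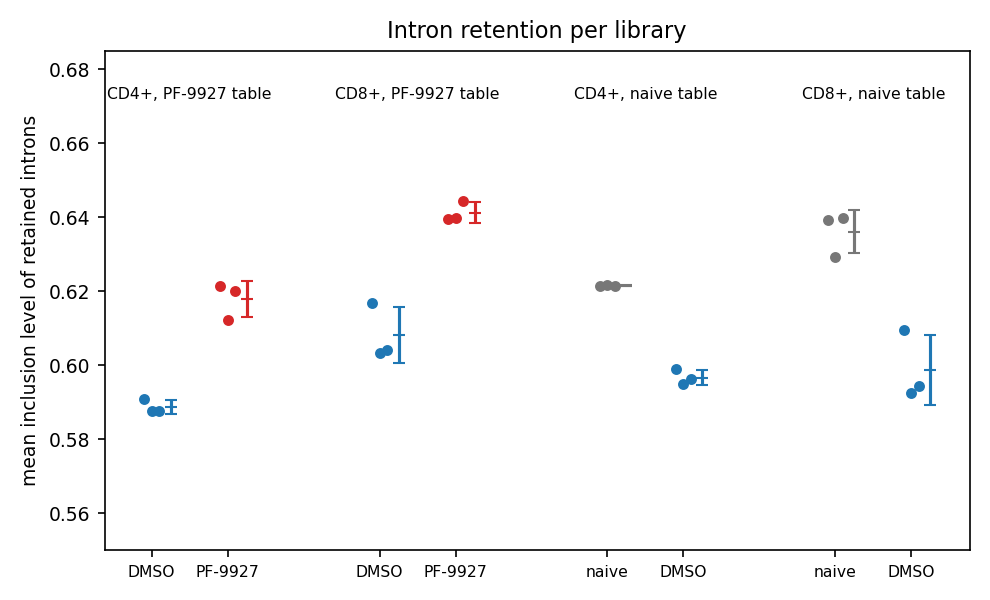
Mean inclusion level of retained introns per library (points), with mean ± SD of 3 libraries beside them. The axis starts above 0. The tables of the comparisons hold different sets of introns, so levels compare only within a pair of groups, and PF-9927 lies above DMSO and naive above DMSO in each pair.

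Single events were tested with limma on logit inclusion levels. In CD4+ cells 23 of 141923 tested events passed (13224 at an unadjusted p under 0.05), all of them alternative 5′ splice sites, with 16 gains and 7 losses of the longer form. In CD8+ cells 8 of 148210 passed, 6 alternative 5′ splice sites and 2 skipped exons. In AURKB, a mitotic kinase, inclusion of the extended exon part on chromosome 17, 8110494 to 8110635, went from 0.987 ± 0.0068 to 0.786 ± 0.0233 (adjusted p = 0.035, mean of 726 reads). CNOT10 (−0.365) and PCBP4 (−0.332) had the largest losses, and FAM115A (0.312) and AGAP2 (0.234) the largest gains in CD4+ cells. In CD8+ cells the largest change was a gain of 0.647 in XPO1, from 0.353 ± 0.359 to 1. The exon of PREB on chromosome 2, 27354542 to 27354699, went from 1 to 0.751 ± 0.0553 (adjusted p = 0.044), and other losses were those of FAM199X (−0.256) and SSNA1 (−0.184). Leaving out any 1 library ended all of these calls. On simulated data the test found 0 of 200 skipped exons changed by 0.4 and 236 of 3000, so low counts here say little about how many events changed.

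A test weighted by counting precision, on events with a mean inclusion of 0.05 to 0.95, was added after the data were seen and found 1338 of 3000 simulated changes of 0.4, with 40 of 1378 calls false. With only 200 events changed it found 18 changes of 0.4 and none of 0.1 or 0.2, where its 4 calls and 1 call were all false. It called 928 events in CD4+ cells (536 gains and 392 losses) and 1351 in CD8+ cells (680 and 671), and leaving out 1 library gave 384 to 716 and 539 to 1573. Of retained introns 109 gained and 2 lost inclusion in CD4+ cells, and 128 gained and 6 lost in CD8+ cells. Of skipped exons 80 gained and 249 lost in CD4+ cells. Of events tested in both lineages, 203 gains and 153 losses were shared, against 6.9 and 4.7 for independent lists. HNRNPC, a splicing regulator, used the longer 5′ splice site of an exon on chromosome 14 (21699117 to 21699155) at 0.138 ± 0.059 with DMSO and 0.432 ± 0.0907 with PF-9927 in CD4+ cells (adjusted p = 1.6e-05), and at 0.130 ± 0.0533 and 0.457 ± 0.074 in CD8+ cells. STAT2, a transcription factor of interferon signalling, retained the intron on chromosome 12, 56743294 to 56743372, at 0.036 ± 0.0151 and 0.159 ± 0.0031 in CD4+ cells (adjusted p = 0.0046). UBA7, the activating enzyme for ISG15, retained an intron at 0.238 ± 0.0424 and 0.632 ± 0.0928 (adjusted p = 0.0022).

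Skipping rose in other named genes under the weighted test. Exon inclusion in XAF1, an interferon-induced gene of apoptosis, went from 0.881 ± 0.0351 to 0.212 ± 0.0578 in CD8+ cells (chromosome 17, 6665205 to 6665356, adjusted p = 6.4e-06). In IL7R the exon on chromosome 5, 35874551 to 35874644, changed by −0.264 in CD4+ and −0.217 in CD8+ cells, and an exon of LAG3 by −0.518 in CD8+ cells. An exon of MDM4 (chromosome 1, 204506558 to 204506625) went from 0.768 ± 0.0663 to 0.284 ± 0.1128 in CD8+ cells (adjusted p = 0.011, mean of 68.7 reads). In PKM, the pyruvate kinase gene, inclusion of the exon on chromosome 15, 72494795 to 72494961, changed by −0.267 and −0.304. Of the splicing factor list, 10 events gained and 3 lost inclusion in CD4+ cells and 13 gained and 10 lost in CD8+ cells, and no event of the PRMT5 or Sm and SMN lists was called in either lineage. In the authors' deposited table, 405 retained introns were higher with PF-9927 and 97 higher with DMSO in CD4+ cells, and 444 and 118 in CD8+ cells, at its FDR of 0.05 and a difference of at least 0.1.

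Activation changed 2614 events in CD4+ cells (1538 gains and 1076 losses of inclusion) and 4075 in CD8+ cells (2143 and 1932), and leaving out 1 library gave 673 to 1263 and 1321 to 3110. Across events, the PF-9927 changes in CD4+ and CD8+ cells had a Pearson correlation of 0.54 over all types and 0.60 for retained introns. For retained introns the PF-9927 change of one lineage correlated with the activation change of the other at −0.256 for CD4+ and −0.211 for CD8+ cells. These are correlations across events, which are not independent replicates.

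Whether genes with changed splicing also changed in expression was asked with Fisher's exact test across genes. Of 15 genes with a called event in CD4+ cells 1 changed in expression, against 4.8% of the rest (odds ratio 1.42, 95% interval 0.034 to 9.39), and of 6 in CD8+ cells 0 did (odds ratio 0, up to 8.44). With the weighted calls the odds ratio was 4.55 (3.35 to 6.12) in CD4+ and 2.13 (1.67 to 2.70) in CD8+ cells. Genes that rose in expression were 13.9% of the genes with a weighted call and 2.8% of the rest in CD4+ cells (odds ratio 5.60), and 9.9% and 3.7% in CD8+ cells (2.88). Genes that fell were 3.0% and 1.5% in CD4+ cells (2.08, 1.03 to 3.85) and 7.3% and 5.2% in CD8+ cells (1.43, 1.00 to 2.01). Read depth raises the power of both tests, and in the upper part of the genes by expression the odds ratios were 4.86 and 2.26, while those of genes that fell were 1.77 (0.718 to 3.82) and 1.47 (0.960 to 2.20), with intervals that include 1.

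The ATAC-seq comparison asked whether PF-9927 changed open chromatin in CD3+ cells at 96 h. Of the promoters of interferon-stimulated genes, 42 of 44 had a called peak within 1 kb of the start of the gene in all 6 libraries. So did 20 of 22 nucleic acid sensing genes and 10 of 18 interferon, receptor and signalling genes. With most of these promoters called in every library, peak presence there leaves little room to show a change. The deposited lists held 130390 ± 14075 distinct peaks per DMSO library and 135408 ± 16061 per PF-9927 library (two-sided exact permutation p = 0.6), covering 56.7 ± 5.31 and 59.6 ± 5.82 Mb (exact p = 0.6). Within replicate numbers the differences in peak number were 12772, −4984 and 7267. Median peak width was 321 bp in both groups (exact p = 1).

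Of 217278 merged regions 75252 had a peak in all 6 libraries. Regions with a peak in all 3 libraries of 1 group and in none of the other numbered 636 for PF-9927 and 413 for DMSO. At a −log10 q of at least 5 the direction turned, with 312 for PF-9927 and 405 for DMSO. It stayed with the same number of top peaks (574 and 364) and with an overlap of 50% of the shorter peak (654 and 468). With all peaks, the other splits of the 6 libraries that part all 3 same-numbered pairs gave at most 431 regions. Splits that keep a pair together gave 1620 to 3881. Only 4 splits part all pairs, the real one included, which is too few to decide about the compound. The base overlap of libraries (Jaccard index) was 0.612 ± 0.028 within groups and 0.631 ± 0.057 between groups (exact permutation p = 0.7 over 10 splits), and 0.693 between libraries with the same number. All 3 same-numbered pairs (0.6885, 0.7373 and 0.6535) lie between groups and raise that mean, so this test decides nothing about the compound. The remaining pairs between groups had 0.5694 to 0.6412, and the pairs within groups 0.5802 to 0.6623. A difference in peak height was not tested: the lists hold no read counts, the fold enrichments are values of each list, and the depth of these libraries is unknown.

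**Figure D4:**
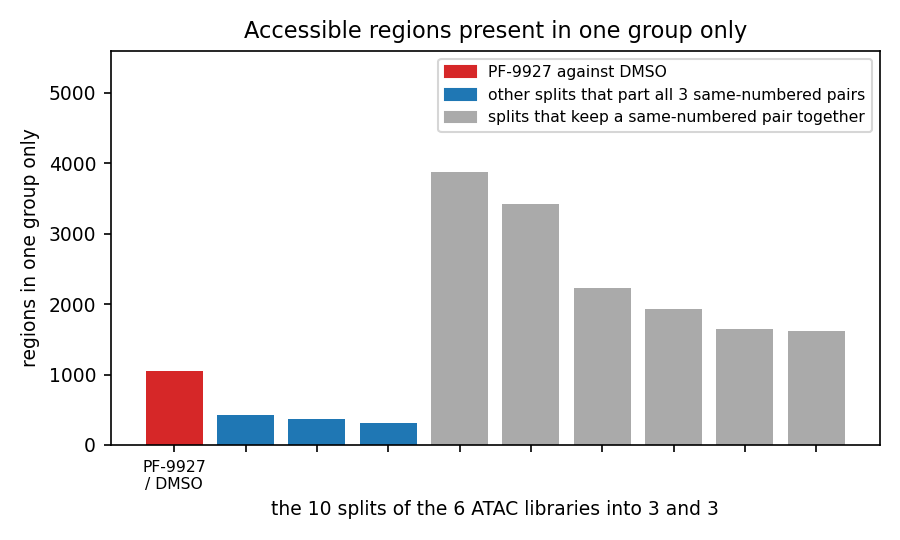
Regions with a peak in all 3 libraries of one group and none of the other, for each of the 10 splits of the 6 ATAC-seq libraries into 3 and 3. The real split gave 1049 regions and the other splits that part the same-numbered libraries up to 431. Splits that keep a same-numbered pair together gave 1620 to 3881. Only 4 splits part all pairs, the real one included, too few to decide about the compound.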

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

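The tests of the 3 patterns weighed here were chosen after the results were seen, except the comparison of intron gains by host expression and the counts of other splits. The weighted splicing test was also chosen after the data were seen.

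The first pattern is the fall of interferon-stimulated genes with PF-9927. A batch marked by the number after the letter L in the labels is argued against as the cause in CD8+ cells, where both groups carry the same number and the list's median was −1.99, but in CD4+ cells (median −1.22) number and compound cannot be told apart. Fewer monocytes or plasmacytoid dendritic cells as carriers of these transcripts stay open. The summed TPM of 17 markers fell by at most 0.0055 of the summed fall of the list, and the falling markers alone by at most 0.009. With DMSO the markers summed to only 51.5 TPM in CD4+ and 155.8 TPM in CD8+ cells, against falls of the list of 2532.5 and 7609.3 TPM. Even a full loss of the markers would have given a small ratio, so it decides nothing. CD68 itself fell in CD8+ cells (−2.02). Scaling of the libraries is argued against by a median of −1.27 or lower in both lineages after quantile normalization. An effect of PF-9927 on interferon production or response, as the hypothesis that the design names, stays open. Fewer monocytes or plasmacytoid dendritic cells as a source of interferon also stay open and were not tested. Isolation of naive T cells speaks against them, but naive CD8+ libraries 1 and 3 held S100A9 at 4587 and 5284 TPM, so purity cannot be taken as given.

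The second pattern is the presence of neutrophil granule transcripts in naive CD8+ libraries 1 and 3, where S100A9 was at 4587 and 5284 TPM against 111 TPM in library 2. Of 12 granule markers of neutrophil precursors, 11 (91.7%) were at least 1 TPM and 4 times library 2 in both libraries. Granule genes drew attention to the pattern, so this count describes it and is no separate test. Precursor cells of the neutrophil lineage stay a candidate explanation, although isolation of naive T cells should remove them. Of 12 markers of mature neutrophils and 10 of monocytes, 2 and 3 met the same limits (22.7% together, exact 95% interval 7.8% to 45.4%), so these types stay undecided. Reads from another library of the series are argued against, since the highest S100A9 level in the other 15 was 108.9 TPM. The design names no biological explanation, and none beside these cell types was tested.

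The third pattern is the higher intron retention with PF-9927. Less complete activation is argued against as the whole cause, because PF-9927 moved genes that rose with activation back by a median of at most 7.1% of their activation change, and genes that fell by 18.5% in CD4+ and 10.6% in CD8+ cells. Unspliced RNA or DNA read evenly over all introns may contribute, but the test does not single it out. The median gain in host genes of the lowest of 4 expression groups was up to 31.86 times that in the highest (0.0223 against 0.0007 in CD4+ and 0.0218 against 0.001 in CD8+ cells). This ratio rests on very small gains in the highest group. The share of introns with a gain differed less, at 71.2% in the lowest and 59.9% in the highest group in CD4+ cells, and 71.0% and 66.1% in CD8+ cells. Per the file headers, 4.941 ± 0.721% of bases were covered with DMSO and 5.905 ± 0.806% with PF-9927 in CD4+ cells. In CD8+ cells it was 5.257 ± 0.413% and 5.643 ± 0.755%. Naive libraries, whose mean retention was also above that with DMSO, had 6.002 ± 0.868% in CD4+ and 6.477 ± 1.09% in CD8+ cells. Whether coverage goes with the retention was not tested. A direct effect of the compound on splicing stays open beside unspliced RNA or DNA, and genes of high expression with a gain, such as HNRNPC at another splice site, were not tested apart.

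Other results stood out because the lineages differed in the test of the difference itself. For the difference in activation between CD4+ and CD8+ cells 19 genes passed by limma, but leaving out 1 library gave 2 to 260. Naive CD8+ libraries 1 and 3, with their neutrophil granule transcripts, enter this difference. The number after the letter L also differs between naive and DMSO libraries of CD8+ cells and cannot be told apart from activation there. The median difference of the PF-9927 effect, CD8+ less CD4+, was −0.73 for stress response genes and 0.34 for cholesterol synthesis genes, but with the replicate block and an estimated correlation neither list passed (adjusted p = 0.069 and 0.054). The median difference of the activation effect was −0.51 for mitochondrial transcripts (adjusted p = 1.5e-12, 0.0050 with an estimated correlation and 0.42 after quantile normalization). In the same test mitotic genes had −0.37 (0.17 with an estimated correlation), p53 targets 0.73 (0.17), stress response genes 0.79 (0.070), interferon-stimulated genes 0.98 (0.93) and monocyte markers −3.73 (0.17).

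The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the only 1 of 10 with as many calls in each expression and splicing comparison. For PF-9927 it called 540 genes in CD4+ cells (highest other split 16, and 0 among those that part all 3 pairs) and 1105 in CD8+ cells (highest other 0). For activation it called 7555 (highest other 0) and 8103 (highest other 1). Splicing gave 23, 8, 2614 and 4075 events against 0 in the other splits, and with the weighted test 928, 1351, 4938 and 7367 against at most 11, 2, 0 and 0. For ATAC-seq regions 7 of 10 splits, the real one included, gave at least 1049. The other 6, up to 3881, keep same-numbered libraries together, which points to a structure of the samples by number. For the difference of PF-9927 effects between lineages the real count was 0, which 100 of 100 drawn splits reach by necessity (highest other 392), so their number decides nothing. For that of activation effects 9 of 100, the real one included, gave at least 19 (highest other 6282). The other 8 keep naive and activated libraries apart in 1 lineage and mix them in the other, in the opposite direction, so they carry the activation effect into the difference. The remaining 91 gave at most 6, but mix naive and activated libraries in at least 1 lineage. These splits decide nothing about chance either.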

How the results depend on the processing

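Chosen after seeing the data were the fit of only the groups compared with the block, the limits of 0.05 to 0.95 on mean inclusion, the weighted splicing test, leaving out naive CD8+ libraries 1 and 3, and keeping only CD4+ libraries of the shared number. Where no cause is given, the cause was not tested.

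Under the alternatives chosen beforehand, activation called 6862 to 8403 genes in CD4+ and 7413 to 8890 in CD8+ cells, within 1.5 times the reported counts. For PF-9927, the replicate block gave 1012 genes in CD4+ cells (536 of the reported 540 among them) and 1900 in CD8+ cells. For the activation difference between lineages it gave 114. Naive and DMSO libraries of CD4+ cells share only a number (correlations of 0.097, 0.22 and 0.087 for equal numbers). Fits of only the groups compared gave 10 genes for PF-9927 in CD4+, 162 in CD8+ cells, 1 for the PF-9927 difference and 5 for the activation difference. With the block as well, the PF-9927 count was 1087 in CD4+ cells (437 of the reported 540 among them) and 1597 in CD8+ cells (823 of the reported 1105). These fits use the same libraries, so fewer libraries alone do not account for the low counts without the block. Without a filter on low values 4 genes passed for the PF-9927 difference and 32 for the activation difference. The latter was 10 with a pseudocount of 0.1, 5 after quantile normalization and 4 without naive CD8+ libraries 1 and 3. Leaving out each library gave 258 to 522 genes for PF-9927 in CD4+ cells, 402 to 1319 in CD8+ cells, 0 to 0 for the PF-9927 difference and 2 to 260 for the activation difference.

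For the genes named in the text, 139 comparisons of a gene past the threshold gave 1727 values under alternatives, of which 1494 kept the direction and the call, 233 lost the call and 0 turned. Leaving out 1 library ended 143 of 834, and fits of only the groups compared 55 of 139. Among genes short of the threshold, the log2 change with PF-9927 crossed 0 on leaving out 1 library for PRMT5 (−0.016 to 0.483 in CD4+ and −0.109 to 0.343 in CD8+ cells) and MKI67 (−0.286 to 0.001 in CD4+ cells). Of 338 values of such genes 14 passed, 9 of them in the fit of only the groups compared with the block, as for CDKN1A in CD4+ cells (adjusted p = 0.0407, over all alternatives 0.0407 to 0.661), and IFNB1 in CD4+ cells passed with a pseudocount of 0.1 (0.0489, range 0.0489 to 0.408). With an estimated correlation, which widens the error of a list, fewer lists passed: 3 of 10 for PF-9927 in CD4+, 1 of 10 in CD8+ cells, 5 of 12 and 7 of 14 for activation, 2 of 11 for the PF-9927 difference and 1 of 9 for the activation difference. The mitochondrial list's PF-9927 difference changed direction after quantile normalization (adjusted p = 0.984).

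No paired analysis was possible for splicing because the table cells carry no replicate number. Events changed by PF-9927 in CD4+ and CD8+ cells and by activation in CD4+ and CD8+ cells numbered 9783, 11216, 14553 and 17508 by the authors' deposited FDR among the events tested here, with at least 10 reads in each library, and 928, 1351, 4938 and 7367 by the weighted test. With mean inclusion of 0.05 to 0.95 and no weights, PF-9927 gave 360 and 588. A minimum difference of 0.2 gave 5 events for PF-9927 in CD8+ cells, 1398 for activation in CD4+ and 2310 in CD8+ cells, and a mean of 10 reads gave 2 for PF-9927 in CD8+ cells. Leaving out each library gave 0 to 0 for PF-9927 in both lineages, 673 to 1263 for activation in CD4+ and 1321 to 3110 in CD8+ cells. The odds ratio of changed splicing and expression was 4.55 in CD4+ and 2.13 in CD8+ cells with weighted calls. Weighted calls of retained introns alone gave 6.28 and 2.28. In the test fixed beforehand, retained introns alone, and skipped exons alone in CD4+ cells, had no called event and gave no odds ratio. Mean intron retention kept its direction when each library was left out, at 0.0274 to 0.032 with PF-9927 in CD4+, 0.0307 to 0.0375 in CD8+, −0.026 to −0.024 with activation in CD4+ and −0.0428 to −0.0342 in CD8+ cells.

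For ATAC-seq, the PF-9927 less DMSO difference in peaks per library was −5317 at a −log10 q of at least 5, with a median width difference of 26 bp (32, 9 and 37 bp within the replicate numbers, exact p = 0.1). Leaving out each library gave a difference of −3857 (without PF-9927 replicate 3) to 12770 peaks, with −971 without DMSO replicate 1, and of −0.108 to 5.915 Mb in summed length. It gave 2327 to 4829 regions in 1 group only, by construction more, as fewer libraries must hold a peak. TPM and peak lists keep no read counts, so the depth behind a single value is unknown there. In splicing, where reads are given, the reported test found 0 of 200 simulated changes and says little about events of any depth.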

Other observations

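The test in the last paragraph was chosen after the related results were seen, and the values before it use the weighted splicing test, also chosen after the data were seen. A few more genes changed form with PF-9927. IL32, a cytokine gene of T cells, used the upstream of a pair of mutually exclusive exons (chromosome 16, 3115643 to 3115827) at 0.144 ± 0.0412 with DMSO and 0.573 ± 0.0501 with PF-9927 in CD4+ cells (adjusted p = 3e-05), and at 0.189 ± 0.0521 and 0.674 ± 0.1408 in CD8+ cells. RNF216, a ubiquitin ligase, gained the longer form of an exon at its 3′ splice site (chromosome 7, 5778984 to 5779256) by 0.545 in CD4+ and 0.529 in CD8+ cells. MKI67 included an exon on chromosome 10, 129913192 to 129914271, at 0.600 ± 0.0937 with DMSO and 0.905 ± 0.0296 with PF-9927 in CD8+ cells (adjusted p = 0.00042), while its expression was at 164 ± 38 and 142 ± 14.6 TPM. Among the few introns that lost retention, that of ILKAP changed by −0.425 in CD4+ and −0.381 in CD8+ cells.

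The CD4 transcript in libraries labelled CD8+ was at 0.233 ± 0.0436 TPM in naive cells, 15.2 ± 10.8 TPM after activation with DMSO and 3.28 ± 3.22 TPM with PF-9927, against 310 ± 51.6 to 342 ± 53.5 TPM in naive and DMSO-treated CD4+ cells.

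A hypothesis was that a retained intron lowers the level of its host gene. The data went the other way: with PF-9927, genes that gained a retained intron had a median log2 expression change of 0.22 in CD4+ and 0.14 in CD8+ cells, against 0.08 and −0.04 for other genes with a tested intron. The smaller of the differences was 0.138. Read depth helps the detection of both changes and was not separated here.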
